A study of Mus musculus with 8 samples.

How the data were processed

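Lung mesenchymal cells of adult, tamoxifen-treated mice were profiled by bulk RNA sequencing, with 4 HhipCKO and 4 Control libraries. Series-level text describes cells sorted by flow cytometry, whereas the labels' extraction protocol speaks of cultured cells, and nothing settles whether a culture step came between. RNA was taken with QIAGEN RNeasy kits and checked on an Agilent Pico chip, and sequencing was done at GENEWIZ, per the labels' protocols. Reads were handled with FastQC, STAR and DESeq on GRCm38, also called mm10, per the submitters' processing notes, which give no versions. Annotation, strand setting and counting tool are not stated there.

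The authors' deposited table has 31607 genes with, per the file headers, a mean normalized count signal over all libraries, a log2 fold change of HhipCKO against Control with its standard error on the log2 scale, a Wald score, a p-value and an adjusted p-value. It holds 0 columns of values per sample. Several properties were checked on the deposited values. The Wald score equals the log2 fold change over its standard error to within 2.56e-07, and the p-value is the matching normal one. Adjusted p-values in the deposited table equal Benjamini-Hochberg values over the 17469 genes that have one. All of those have a mean normalized count signal of at least 42.1 in the deposited table, and genes with a p-value below that limit have none. A further 150 genes have no p-value, as happens when single counts are set aside as outliers. Genes listed have at least 2 counts in all, judged from the steps of the lowest values.

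Depth per library is not given. Genes whose counts all come from 1 library form 8 separate levels among the lowest values, 4 with positive and 4 with negative fold changes. Taking 2 counts as the content of each level gives the size factors. Those of all 4 HhipCKO libraries exceeded those of all 4 Control libraries, and the mean was 7.93% higher (two-sided exact permutation test, p = 0.0286, the smallest that 70 arrangements allow). Relative factors do not depend on the assumed 2 counts.

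Tests planned on values per sample, including an exact permutation test of Hhip, limma or count-model fits, estimated inter-gene correlations and rotation tests, could not be run on a table of this kind. The authors' own Wald tests were used in their place, at an adjusted p of 0.05. Folds and 95% intervals were computed from each log2 fold change and its standard error under a normal distribution. No SD or value per library was at hand to check them, so precision rests on the authors' fit alone.

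Gene lists, 37 in number, were fixed before the data were examined, 20 of pathways or functions, 15 of cell types and 2 of sample quality. Of 826 entries, 5 were matched through another symbol and 2 were not found. For a repeated symbol the entry with the highest mean normalized count was taken, and Hhip was left out of the lists that held it. Each list was tested with cameraPR (limma 3.58.1, R 4.3.3) on the Wald scores of all tested genes with a preset inter-gene correlation of 0.01, and the p-values were adjusted by Benjamini-Hochberg over the 37 lists. An inter-gene correlation could not be estimated without values per sample, so 0.05 and a rank version served as alternatives. For every list, the p-value of this test does not measure the spread between libraries. List medians were also set against 10000 random lists drawn within 10 bins of mean count by 10 bins of transcript length.

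The 65 named genes were chosen by a rule fixed beforehand. It takes Hhip, hedgehog targets past the threshold with pathway genes such as Gli1 and Ptch1 in any case, and the 10 largest rises and 10 largest falls with a mean normalized count of at least 50 and a symbol that is not a predicted model. From every other list it takes up to 4 members with the smallest adjusted p, plus Il7, Tslp, Il33, Cxcl12 and Myh11. Its further demand that the values of the groups do not overlap could not be applied. Other list members given with values, such as Foxd1, Smo, Col1a1, Atf4 and Mx1, lie outside this rule. Col11a1 and Usp18 were among those picked by their values.

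Coordinates and transcripts came from GENCODE M21 on GRCm38, the build the submitters name, and 31555 gene identifiers matched. The longest annotated transcript gave a length for 99.8% of tested genes. To remove the length trend, a lowess curve of log2 fold change on log10 length with a span of 0.3 was subtracted and p recomputed with the same standard error (Python 3.11.15, statsmodels 0.14.6). Neighbouring genes were scanned in windows of 10 with 1000 shuffles of the gene order.

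The steps were tested on simulated Wald scores for the 17469 genes with their own standard errors and 200 changed genes. For log2 changes of 0.5, 1 and 2 the calls recovered 22, 61 and 89% of the changed genes. With a length trend added, false calls made up 56.6% of the genes called at a log2 change of 1, and 5.67% once the trend was removed. The simulation used independent normal noise and a trend straight in log10 length. The real Wald scores spread more widely, with a robust SD of 1.53, and of 1.32 with the trend removed. The simulated shares therefore do not carry over to the real calls.

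Alternatives were median-centred fold changes, no filter on low values, and a 1.5-fold minimum, all planned, and minimum mean counts of 50 and 500, removal of the length trend and division of the statistics by their robust SD, all chosen after seeing the data.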

Results

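Bulk RNA sequencing was used to profile lung mesenchymal cells of adult mice in which Hhip had been deleted after tamoxifen. Hhip encodes a membrane protein that binds hedgehog ligands and so limits signalling to the cells around it. The HhipCKO mice carried floxed Hhip alleles with tamoxifen-activated recombinase drivers, among them Myh11-creER, which is expressed in smooth muscle. Control mice carried the floxed alleles without a driver. Live cells lacking CD45, CD31 and Epcam, the surface markers of leukocytes, endothelium and epithelium, were sorted, and 4 libraries were made per group. All values come from the authors' deposited table, which holds 1 comparison of the groups and no value per library. Its mean normalized counts sum to 128669692 per library over 31607 genes. Library size factors recovered from the lowest values lay between 1.03 and 1.06 for the HhipCKO libraries and between 0.939 and 1.004 for the Control libraries. The question was how loss of the inhibitor altered transcription in the sorted mesenchyme.

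Hhip was strongly reduced in the HhipCKO libraries. In the authors' deposited table its log2 fold change was -2.62 ± 0.32 (SE), a level 6.15-fold lower with a 95% interval from 3.99 to 9.49, at an adjusted p of 9.55e-13. About 16.3% of the Control level remained. The gene (ENSMUSG00000064325) lies on the minus strand of chromosome 8 from 79965851 to 80058006 on GRCm38. The table gives a single value for the whole gene, so reads from floxed and remaining exons cannot be separated, and the level in each library was not analysed here.

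Of 17469 genes with an adjusted p in the authors' deposited table, 534 rose and 685 fell at 0.05, or 6.98% in all. The changes were mostly small. The median size among these 1219 genes was 0.51 on the log2 scale, and 196 changed at least 2-fold, 65 upwards and 131 downwards. The count depended on how the fold changes were treated. With a trend on transcript length removed, a choice made after seeing the data, 539 genes passed, and 18 passed when the Wald statistics were divided by their robust SD of 1.53.

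Hedgehog target genes rose as a group. Of 19 tested members of a list fixed before the data were examined, 5 rose, 1 fell and 13 did not pass over all genes tested, and adjusted over the list alone 7 rose and 1 fell. Ptch1, the hedgehog receptor and itself a transcriptional target, was 2.53-fold higher with a 95% interval from 1.66 to 3.85 in the authors' deposited table (log2 fold change 1.34 ± 0.31 SE, adjusted p = 0.00132). Gli1, the transcription factor most used as a readout of the pathway, rose less, by 1.35-fold with an interval from 1.16 to 1.59 and an adjusted p of 0.00693 in the authors' deposited table. The forkhead genes Foxl1 and Foxd2 had log2 fold changes of 0.98 ± 0.19 and 1.44 ± 0.35 (SE) in the authors' deposited table. Ccnd2, a D-type cyclin, went the other way, with a log2 fold change of -0.57 ± 0.14 (SE) and an adjusted p of 0.00348 in the authors' deposited table. Foxd1 and Foxf1 stood at 1.08 ± 0.39 and 0.30 ± 0.11 (SE) in the authors' deposited table and missed the threshold, with adjusted p of 0.0644 and 0.0683. On GRCm38, Ptch1 (ENSMUSG00000021466) lies on chromosome 13 from 63508328 to 63573598 and Gli1 (ENSMUSG00000025407) on chromosome 10 from 127329882 to 127341974.

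The median log2 fold change of the hedgehog list was 0.30. It lay above nearly all of 10000 random lists matched on mean count and transcript length. The competitive list test gave an adjusted p of 0.00175 (limma's cameraPR on the authors' Wald statistics, Benjamini-Hochberg over 37 lists), and 0.0311 with an inter-gene correlation of 0.05. None of the 6 single-gene calls passed when the statistics were divided by their robust SD. Ccnd2 no longer passed with the length trend removed, at -0.42 and an adjusted p of 0.0731.

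**Figure D1:**
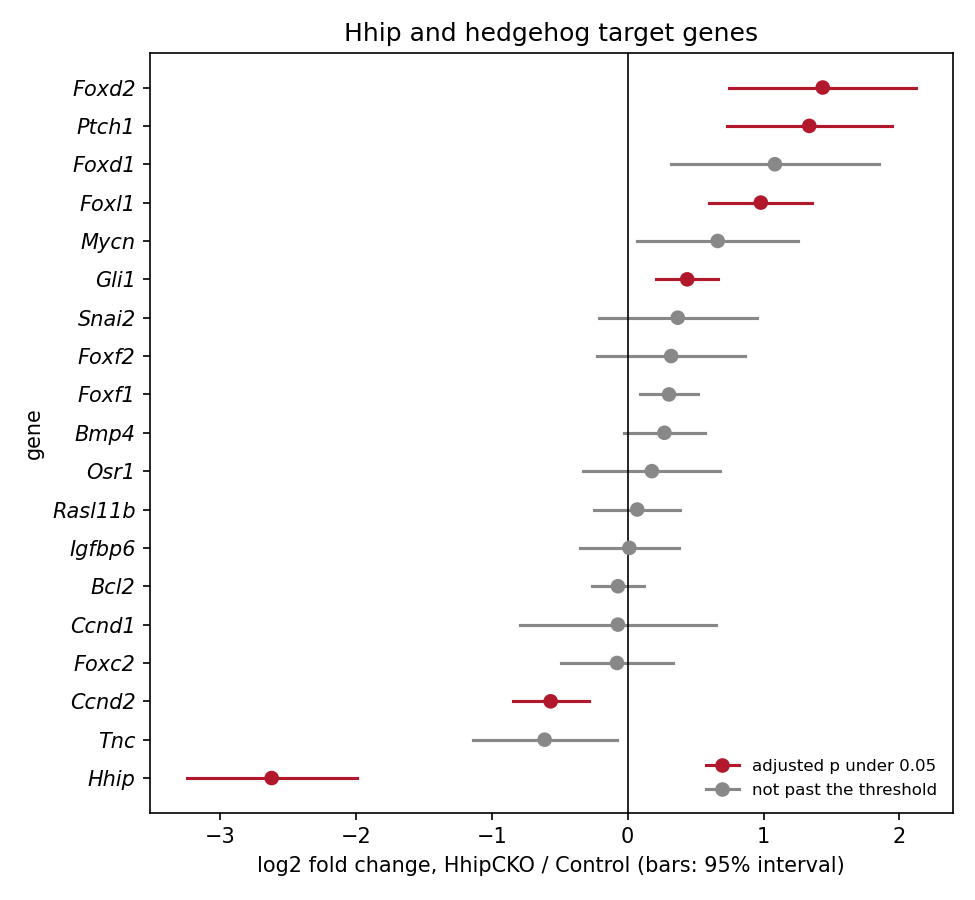
Log2 fold change of HhipCKO against Control from the authors' deposited table for Hhip and 18 of the 19 tested hedgehog targets, with points at the estimate and bars for the 95% interval. Hhip lies lowest at -2.62, while Foxd2 at 1.44 and Ptch1 at 1.34 lie highest.

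In a separate list of 16 tested hedgehog ligands, receptors and effectors, Gli3, which encodes the main repressor form of the Gli factors, was the 1 gene past the threshold, at -0.28 ± 0.08 (SE, adjusted p = 0.0230) in the authors' deposited table. That call was lost with the length trend removed, at -0.062 and an adjusted p of 0.805. Smo and Sufu, the signal transducer and a negative regulator of the pathway, had log2 fold changes of 0.05 ± 0.10 and -0.01 ± 0.10 (SE) in the authors' deposited table. The ligands themselves were measured imprecisely, with Ihh at 1.14 ± 0.55, Dhh at -1.01 ± 0.61 and Shh at 0.69 ± 0.71 (SE) in the authors' deposited table, none past the threshold. The list's median and mean were positive while its list test pointed down without passing (adjusted p = 0.936, limma cameraPR).

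Mesenchymal signalling genes moved singly and not as groups. Il7, a cytokine that sustains lymphocytes, was 1.83-fold higher with a 95% interval from 1.36 to 2.47 and an adjusted p of 0.00314 in the authors' deposited table. It was the 1 call among 31 tested lymphocyte cytokines and chemokines. The alarmins Tslp and Il33 had log2 fold changes of -0.11 ± 0.23 and -0.31 ± 0.36 (SE) in the authors' deposited table, and Cxcl12 had 0.22 ± 0.14, none of them past the threshold. Of 34 Wnt pathway genes, the ligands Wnt5b and Wnt4 rose, at 0.68 ± 0.12 and 0.86 ± 0.20 (SE) in the authors' deposited table, and the co-receptor Lrp6 fell, at -0.35 ± 0.09. Lrp6 did not pass with the length trend removed (-0.097, adjusted p = 0.690). Among single calls in other signalling lists, the authors' deposited table had the growth factor Tgfb3 at 0.46 ± 0.14 (SE), the BMP antagonist Grem1 at -0.95 ± 0.24 and the neurotrophin Bdnf at -0.76 ± 0.25. Plk2, a p53-induced kinase, rose by 0.85 ± 0.22 and Igfbp7, a secreted binding protein, by 0.51 ± 0.14 (SE) on the log2 scale in the authors' deposited table. With the length trend removed Bdnf missed the threshold at a similar value, -0.73 (adjusted p = 0.0786), and Igfbp7 at a smaller one, 0.36 (adjusted p = 0.146).

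Matrix genes were lower as a list, though the list's most abundant collagens were level. Of 28 genes for collagens and fibrillar matrix, 3 fell, none rose and 25 did not pass, and 4 fell adjusted over the list alone. The fallen genes in the authors' deposited table were Spp1, the secreted phosphoprotein osteopontin, at -1.10 ± 0.30, Col12a1 at -0.78 ± 0.22 and Col6a3 at -0.55 ± 0.17 (log2 fold change, SE). The list's lowest value was that of the cartilage collagen Col11a1, at -2.16 ± 0.74 (SE, adjusted p = 0.0501) in the authors' deposited table. Chondrocyte markers, described below, were lower too, and the matrix list was not tested apart from them. The fibrillar collagens Col1a1, Col1a2 and Col3a1, the most abundant of the list's collagens, had values of -0.09 ± 0.20, -0.02 ± 0.19 and 0.02 ± 0.18 (SE) in the authors' deposited table. The list test gave an adjusted p of 0.00127 (limma cameraPR), and 0.0311 with an inter-gene correlation of 0.05. Many of these messages are long, and fold changes fell with transcript length across all genes. Against random lists matched on length and mean count the list's median of -0.19 stood at percentile 8.46, and Col12a1 and Col6a3 no longer passed with the length trend removed, at -0.47 and -0.28 with adjusted p of 0.263 and 0.460. The list test still passed with the trend removed (adjusted p = 0.0226, limma cameraPR). In the list for elastic fibres and crosslinking, the crosslinking enzyme Loxl4 and the microfibril gene Fbn2 fell, at -1.18 ± 0.22 and -1.95 ± 0.45, and Fbln5 rose, at 0.33 ± 0.11 (SE), in the authors' deposited table. Fbln5 lost its call with median-centred fold changes (adjusted p = 0.0571), without a filter (0.0693) and under a 1.5-fold minimum. It kept the call with the length trend removed, at 0.45 (adjusted p = 0.00405).

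Genes of the unfolded protein response were lower as a list. Of 21 tested genes, 3 fell and 18 did not pass, while 8 fell adjusted over the list alone. The endoplasmic reticulum chaperone Hyou1 had a log2 fold change of -0.98 ± 0.26, Creld2 of -0.82 ± 0.28 and Sdf2l1 of -0.76 ± 0.25 (SE) in the authors' deposited table. Without a filter on low values Creld2 and Sdf2l1 did not pass, at adjusted p of 0.0786 and 0.0576. The list's median was -0.39, with an adjusted p of 0.00175 (limma cameraPR) and of 0.0311 with an inter-gene correlation of 0.05. The stress transcription factors Atf4 and Ddit3 had values of 0.09 ± 0.18 and -0.16 ± 0.27 (SE) in the authors' deposited table.

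Markers of mesenchymal subtypes were mostly level. No list of contractile, alveolar, adventitial, peribronchial or mesothelial genes passed the list test (lowest adjusted p = 0.470, limma cameraPR). Myh11, the smooth muscle myosin whose promoter drives a recombinase in the HhipCKO mice, had a log2 fold change of -0.14 ± 0.33 (SE, adjusted p = 0.854) in the authors' deposited table. The smooth muscle coactivator Myocd fell, at -1.22 ± 0.31 (SE, adjusted p = 0.00334) in the authors' deposited table, and Ly6a, which encodes the adventitial surface marker Sca-1, rose 2.31-fold with a 95% interval from 1.75 to 3.05. Pericyte markers were the exception. Of 18 tested, 2 fell, 1 rose and 15 did not pass, the same numbers as adjusted over the list alone, and 17 had negative values, with a median of -0.43. The integrin Itga1 and the channel Trpc6 each had a value of -0.90, with SEs of 0.17 and 0.27, and the potassium channel gene Kcnj8 one of 0.53 ± 0.13 (SE), in the authors' deposited table. The pericyte list had an adjusted p of 0.000948 (limma cameraPR) and of 0.0236 with an inter-gene correlation of 0.05.

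Cartilage genes showed the largest group difference. Of 11 tested chondrocyte markers, 6 fell and all 11 had negative values, with a median of -1.96, and all 11 fell adjusted over the list alone. In the authors' deposited table the log2 fold changes of Acan, Hapln1 and Col9a1, which encode cartilage matrix proteins, were -2.40 ± 0.79, -2.27 ± 0.53 and -2.18 ± 0.63 (SE). Col11a2 and 3110079O15Rik, now named Snorc, had -1.86 ± 0.48 and -1.96 ± 0.57 (SE) in the authors' deposited table. The list test gave an adjusted p of 6.05e-08 (limma cameraPR), and 8.89e-06 with an inter-gene correlation of 0.05. The correlation among these markers could not be estimated without values per library, so the size of these p-values is uncertain. Glial and neuronal markers were lower too, with 2 of 14 past the threshold. Among them was the receptor gene Gpr17, at -1.02 ± 0.34 (SE) in the authors' deposited table, which did not pass with the length trend removed (-0.93, adjusted p = 0.103) or without a filter (adjusted p = 0.0659). The list's adjusted p was 0.0443 and lost the threshold, at 0.156 with an inter-gene correlation of 0.05, 0.0589 with median-centred fold changes and 0.364 at a mean count of at least 500 (limma cameraPR).

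Lists of interferon-stimulated genes, macrophage and monocyte markers, immune cell markers and interferon-gamma targets were shifted upwards, with 1 member past the threshold in all. All 28 tested interferon-stimulated genes had positive values, with a median of 0.76, yet none passed alone, and none did adjusted over the list alone. Ifi44 and Irf7 of this list and Cd74 and H2-Ab1 of the interferon-gamma list have no p-value in the authors' deposited table, as happens when a count in a single library is set aside as an outlier. Of the fixed lists' genes 7 were in this state, all 7 with positive values, and errors were wide among tested members too, as for Mx1 at 1.90 ± 0.88 (SE) in the authors' deposited table. Usp18, an interferon-induced protease, came closest, at 1.41 ± 0.50 (SE, adjusted p = 0.0627) in the authors' deposited table. The list test gave an adjusted p of 0.00127 (limma cameraPR) and 0.0311 with an inter-gene correlation of 0.05. It compares genes and does not measure the spread between libraries. A rise in a single HhipCKO library therefore cannot be told apart from a rise in all of them, for this list or the other 3. Macrophage and monocyte markers had a median of 1.15 over 19 tested genes, of which the chemokine receptor Ccr2 passed, at 1.70 ± 0.58 (SE, adjusted p = 0.0499) in the authors' deposited table. That call was lost with median-centred fold changes (adjusted p = 0.0518), without a filter (0.0846) and with the length trend removed (0.0553), where its value was larger, at 1.82. Medians were 0.84 for the immune cell markers and 0.41 for interferon-gamma targets and antigen presentation, with no member of either list past the threshold. For these 3 lists the adjusted p were 0.0215, 0.0443 and 0.0443, and with an inter-gene correlation of 0.05 they were 0.125, 0.197 and 0.207 (limma cameraPR). Among genes with a mean count of at least 500 they were 0.590, 0.702 and 0.0865. Lymphocyte markers did not pass, with a median of 0.26, 9 positive and 5 negative values and an adjusted p of 0.801 (limma cameraPR). Lists for cholesterol biosynthesis and for the NF-kB and inflammatory response had medians of 0.25 and -0.18 and adjusted p of 0.0246 each, which became 0.147 and 0.156 with an inter-gene correlation of 0.05 (limma cameraPR). The single call in them was complement C3, at -0.54 ± 0.18 (SE, adjusted p = 0.0469) in the authors' deposited table. Complement C3 did not pass with the length trend removed (-0.46, adjusted p = 0.161). Of the 27 genes in the NF-kB and inflammatory list, 25 were tested. The fixed lists' genes without a p-value, which entered no list test, included the inflammatory genes Lcn2 and Saa3. These stood at 2.53 ± 1.19 and 2.12 ± 1.10 (SE) in the authors' deposited table.

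The genes used for the negative sort did not differ detectably. Ptprc, Pecam1 and Epcam, which encode CD45, CD31 and Epcam, had log2 fold changes of 0.54 ± 0.55, -0.40 ± 0.25 and 0.59 ± 0.48 (SE) in the authors' deposited table. With errors this wide, a rise of Ptprc as large as the immune cell list's median of 0.84 is not excluded. Equal leukocyte content of the groups therefore cannot be read from it. Single calls in epithelial lists were Akap5 at -0.98 ± 0.33 and the mucin Muc5b at -1.26 ± 0.35 (SE) in the authors' deposited table. Neither passed with the length trend removed, at -0.82 and -0.89 with adjusted p of 0.157 and 0.147. Values in the alveolar epithelial list were positive for 15 genes and negative for 10, with a median of 0.23. In the airway list they were positive for 6 and negative for 9, with a median of -0.13. Against matched random lists the medians stood at percentiles 99.99 and 3.88, but neither list passed the list test. Of the sex-linked genes, Y-linked Uty rose, at 0.64 ± 0.18 (SE, adjusted p = 0.00935) in the authors' deposited table. Xist, expressed in females, had a mean normalized count of 55.2 and Y-linked Ddx3y one of 11959 in the authors' deposited table. The remaining lists among the 25 that did not pass the list test included cell cycle genes, with a median of 0.25, and dissociation and immediate-early genes, with a median of 0.01, and neither held a call.

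**Figure D2:**
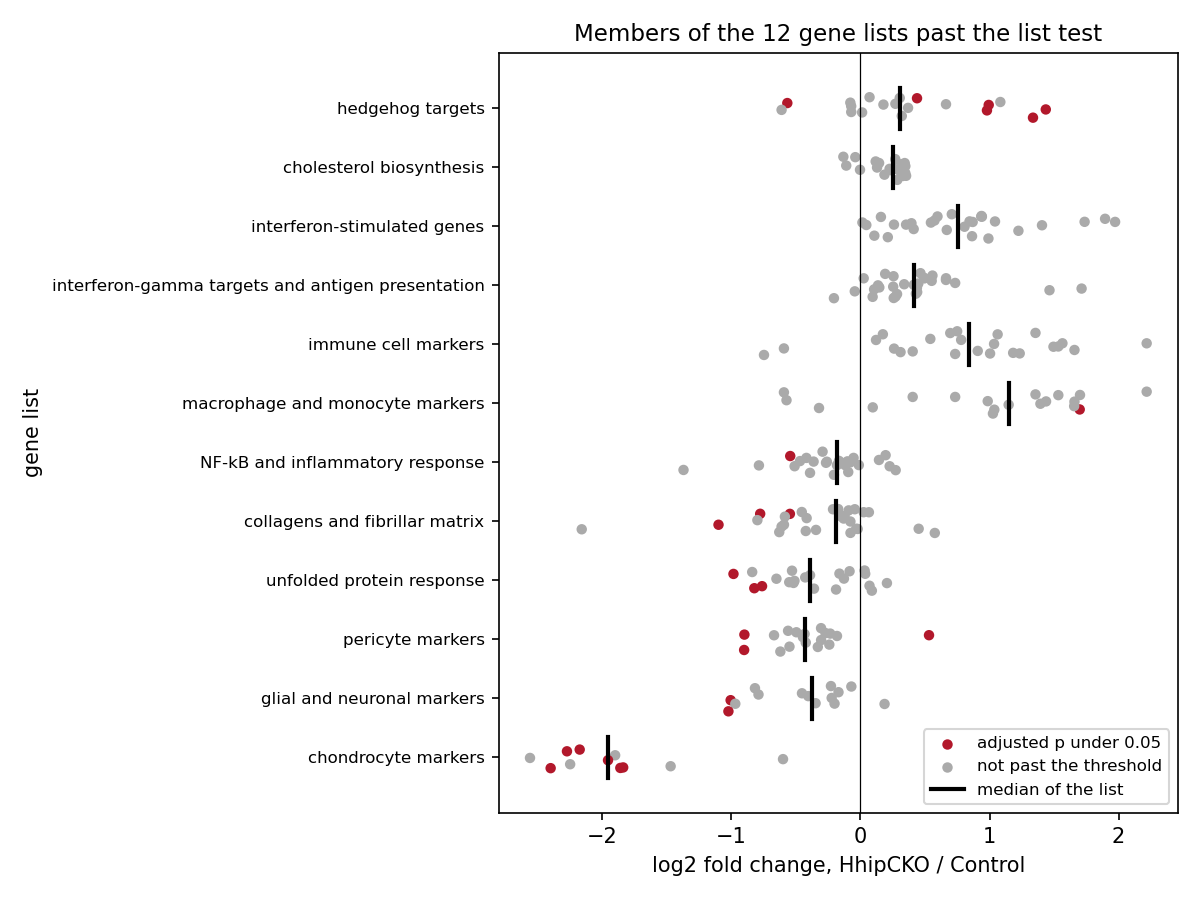
Log2 fold change of HhipCKO against Control from the authors' deposited table for the tested members of the 12 lists past the list test. Each point is a gene, red points have an adjusted p under 0.05, and black bars mark medians, which run from -1.96 for chondrocyte markers to 1.15 for macrophage and monocyte markers.

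Among genes with a mean normalized count of at least 50 and a symbol that is not a predicted model, the 10 largest rises included genes of leukocytes. In the authors' deposited table these were the immunoglobulin genes Ighg3 and Iglv3, at 4.80 ± 1.62 and 2.75 ± 0.78 (SE), the adhesion receptor Adgre4 at 2.31 ± 0.73, the kinase Fgr at 2.25 ± 0.54 and the RNA sensor Tlr7, in a block of higher X-linked genes, at 2.64 ± 0.80. The mean normalized counts of these leukocyte genes were low, from 63.0 for Tlr7 to 174.8 for Ighg3 in the authors' deposited table. The median over tested genes was 1810. Which cells these transcripts came from, and in how many libraries, was not tested. Interferon-inducible Ifi44l stood at 3.22 ± 0.91 and the neuropeptide gene Grp at 2.77 ± 0.79 (SE) in the authors' deposited table. Ighg3 and Adgre4 lost the threshold with the length trend removed, at adjusted p of 0.0817 and 0.0523, while their values barely moved, to 4.72 and 2.30. Among these 10 rises the smallest adjusted p belonged to Iyd, an iodotyrosine deiodinase, at 2.63 ± 0.32 (SE, adjusted p = 7.38e-13) in the authors' deposited table. AI593442 had 2.50 ± 0.41 and Ibsp, a bone sialoprotein, 2.36 ± 0.53 (SE) in the authors' deposited table.

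With the same limits on count and symbol, the largest falls beside Hhip and Acan in the authors' deposited table were Ugt1a1, a bilirubin-conjugating enzyme, at -4.56 ± 1.43, the collagen Col25a1 at -2.73 ± 0.64, Lrrc61 at -2.54 ± 0.48 and the transcribed pseudogene Itih5l-ps at -2.50 ± 0.58 (SE). The betaine transporter Slc6a12 stood at -2.47 ± 0.40, the potassium channel Kcnc2 at -2.38 ± 0.80, Meltf at -2.36 ± 0.61 and the cartilage collagen Col10a1 at -2.33 ± 0.76 (SE) in the authors' deposited table. Kcnc2, Acan and Col10a1 missed the threshold with the length trend removed, at adjusted p of 0.0869, 0.0969 and 0.0567, though their values stayed about as large, at -2.30, -2.22 and -2.36. Ugt1a1 shares its last exons with other genes of its cluster, so its reads are uncertain.

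Fold changes followed transcript length across the genes. The median log2 fold change was 0.20 in the 1744 genes with the shortest transcripts, of up to 953 bases, and -0.22 in the 1744 with the longest, of 6478 bases or more. Among the shortest 111 genes rose and 39 fell, against 15 and 300 among the longest. Across 17439 genes, which are not independent replicates, Spearman's rho of the Wald statistic with the length of the longest transcript was -0.38. With a smooth trend removed, 437 of the 1219 genes still passed and 102 others joined them. With fewer small p-values the adjustment is stricter, so some genes lost their call with little change in their value.

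**Figure D3:**
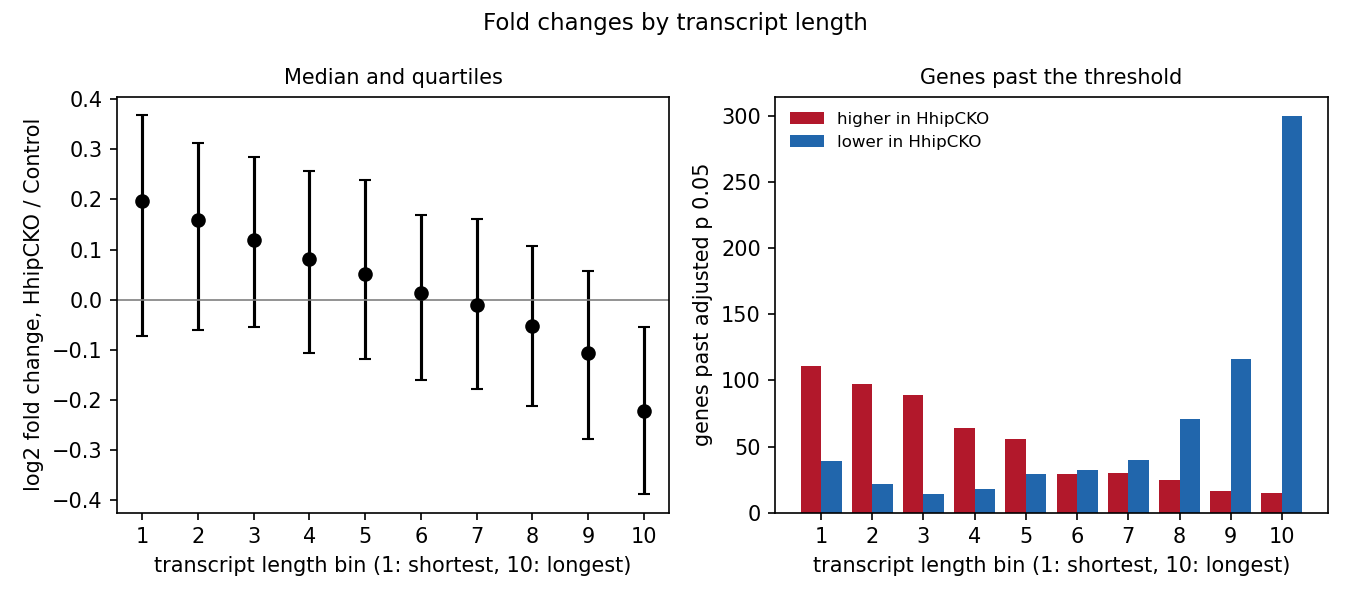
Genes in 10 bins by the length of their longest transcript, with the median and quartiles of the log2 fold change of HhipCKO against Control (left) and the number of genes past an adjusted p of 0.05 in each direction (right), from the authors' deposited table. The median runs from 0.20 in the shortest bin to -0.22 in the longest, where 300 genes were lower and 15 higher.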

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

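Adjusting over all genes was planned, while singling out those below the limit was chosen after the values were seen. Signal outside the main comparison appears among genes with a p-value but no adjusted p, which the mean count limit left out. When Benjamini-Hochberg was applied to all 31457 p-values, 50 of these genes passed, 22 higher and 28 lower in HhipCKO. The smallest p belonged to C130021I20Rik, with a log2 fold change of -7.11 ± 1.25 (SE) at a mean normalized count of 12.2 in the authors' deposited table. Cd300e, a myeloid receptor, followed at 4.09 ± 0.81 (SE) and a mean normalized count of 37.3 in the authors' deposited table. At such counts a single library can decide the value, and values per library were not analysed here.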

How the results depend on the processing

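Minimum mean counts of 50 and 500, the length correction, the robust SD and the other list settings were chosen after seeing the data. Removing the length trend left 539 genes past the threshold (231 higher, 308 lower), dividing the statistics by their robust SD left 18 (7 higher, 11 lower), and a 1.5-fold minimum left 498 (174 higher, 324 lower). The last follows from its construction, while the length correction takes out a trend seen in all genes. For the robust SD the cause was not tested. The other settings gave 960 to 1264 genes. Hhip kept its direction and its call throughout. Hedgehog calls numbered 4 with the 1.5-fold minimum, which Gli1 and Ccnd2 miss, 0 with the robust SD and 5 or 6 otherwise, and the list's adjusted p ranged from 0.000127 to 0.0468 (limma cameraPR). Lists past the threshold fell from 12 to 6 with an inter-gene correlation of 0.05 and numbered 8 to 13 otherwise. Dividing all statistics by a constant cannot change the list test, so the robust SD was no check on the lists. Of 65 named genes, 17 lost their call and 1 turned direction with the length trend removed (Myh11, to 0.013, never past the threshold). With median-centred fold changes 2 lost it (Fbln5 and Ccr2). Without a filter 14 did, among them Ighg3, Adgre4, Acan, Kcnc2, Col10a1, C3, Bdnf, Akap5 and Gpr17. The 1.5-fold minimum cost 10 their call and the robust SD 58. No paired analysis was possible because the table holds no values per library. For the same reason other scalings, count models, sample weights, pseudocounts, covariates, leaving out each library and other splits of the samples were not run, so chance was not examined by regrouping libraries, and depth per library sets no stated limit.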

Other observations

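The genes in this paragraph were chosen after their values were seen. So were Hccs, Arhgap6 and Prps2 below and the tests on GC content, genomic length, sex and extra copies. Fcgr4, an Fc receptor, had a log2 fold change of 2.08 ± 0.49 (SE, adjusted p = 0.00167) at a mean normalized count of 87.7 in the authors' deposited table. Serpina3g and Ifi27l2a, both interferon-inducible, stood at 1.33 ± 0.39 and 1.43 ± 0.46 (SE) in the authors' deposited table. Neither passed with the length trend removed, at 1.21 and 1.23 with adjusted p of 0.0564 and 0.121, nor did Ifi27l2a over all genes, at 0.0592. Nrtn, a ligand of the GDNF family, rose by 1.55 ± 0.23 and the limb transcription factor Pitx1 by 1.62 ± 0.36 (SE) on the log2 scale in the authors' deposited table. Prg4, the joint lubricant lubricin, fell, with -1.68 ± 0.35 (SE, adjusted p = 0.000237) in the authors' deposited table. Ribosomal protein genes, which have short transcripts, had a median of 0.25, and 27 of 79 rose and 1 fell. Their median was 0.11 with the length trend removed.

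The trend of fold changes with transcript length is a first pattern to follow up. It did not follow GC content (rho with the Wald statistic 0.0067), and genomic length had a partial rho of only -0.019 with transcript length held fixed. With genomic length, GC content and mean count held fixed, the partial rho with transcript length was -0.29. A difference in RNA integrity or fragment selection between the groups' libraries is a candidate explanation. Any cause acting through transcript length would give such a value, so it does not single this one out. An effect of the genotype on long messages stays open and untested. Without values per library it is unknown whether all 4 libraries of a group share the trend.

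A second pattern is a block of higher genes near the end of the X chromosome. From 167304929 to 169370003 on GRCm38, 6 of 9 tested genes rose and none fell, among them the genes with the smallest adjusted p of the authors' deposited table, Hccs at 1.13 ± 0.13 and Arhgap6 at 0.85 ± 0.09 (SE), and also Prps2 at 0.89 ± 0.12. The 10-gene window there had a mean length-corrected Wald statistic of 3.56, above the largest window of every shuffle (permutation p = 0.001, the smallest that 1000 shuffles can give), and the next window reached -1.91. That window also held Tmsb4x, outside the interval, at 0.16 ± 0.23 (SE) in the authors' deposited table. The interval's borders fall on the risen genes Tlr7 and BC022960, so the share of 6 of 9 depends partly on them. Tlr7, at 2.64 ± 0.80 (SE) and a mean normalized count of 63.0 in the authors' deposited table, is also among the leukocyte genes above. Its rise need not belong to the block. Female mice in the HhipCKO group are argued against by the 4 Y-linked genes of the fixed list, with a median of 0.18 and a lowest value of -0.04, and by the mean Xist count of 55.2, the length trend by the 5 genes that passed without it, and an extra copy of every gene by Msl3, whose 95% interval ended at 0.024. A smaller or broken duplication, or different sex chromosome backgrounds of the crosses, may remain, since Y-linked Uty rose while genes beyond the block fell. Y-linked Gm29650 rose too, at 0.76 ± 0.26 (SE, adjusted p = 0.0457) in the authors' deposited table, but not with the length trend removed (adjusted p = 0.221). Y-linked Eif2s3y, Ddx3y and Kdm5d did not pass, at 0.29 ± 0.11, 0.07 ± 0.12 and -0.04 ± 0.10 (SE) in the authors' deposited table. On the X, Gm15726 fell at -1.34 ± 0.38 and Gm15247 at -0.88 ± 0.25 (SE) in the authors' deposited table. On the Y chromosome, Mid1-ps1 fell at -1.08 ± 0.31, Gm21742 at -1.49 ± 0.33 and Gm21748 at -1.51 ± 0.48 (SE) there. A widely used Myh11-creER transgene is carried on the Y chromosome, and whether the driver here is, which would give the groups different Y chromosomes, was not tested. Beyond the block Mid1 and G530011O06Rik had -0.68 ± 0.27 and -1.12 ± 0.39 (SE) in the authors' deposited table and did not pass. Arhgap6 overlaps Hccs and the antisense gene Gm15261, so their reads may be shared. By their coordinates Gm15726, Gm15247 and G530011O06Rik lie within Mid1, and Gm21748 lies within Gm21742. Mid1-ps1 is by its name a Mid1 pseudogene. Reads may be shared here too, so these falls need not be separate.

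Another pattern is the fall of cartilage genes, for which fewer cartilage cells in the HhipCKO libraries is a hypothesis. With the length trend removed the list's median was -2.14, which argues against that trend as its source. A further list of 12 cartilage genes, written before its values were seen, had a median of -0.46 (quartiles -0.96 and -0.39). All 12 were negative and 1 passed, Col9a3. The bound set against the hypothesis was a median above -0.5, met by less than the spread. That the bound must be met beyond the spread was added after this median was seen, and by the median alone the hypothesis would have been excluded. The list also held genes that fibroblasts also express, so cell number and lower transcription in the same cells cannot be told apart.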
